A study of Mus musculus with 2 samples.

How the data were processed

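Unfertilised oocytes were collected from wild-type and Mul1 knockout C57BL/6 mice, and RNA of 1 pool per genotype was hybridised to 1 array, as the labels give it, with 213 oocytes in the wild-type pool and 123 in the knockout pool. Each genotype therefore has 1 array, and the replicate number 1 in each group only names the array. Per the labels' protocols, total RNA was purified with RNeasy columns and cRNA was amplified and labelled with Cy3 in a low-input Agilent kit. The arrays were of Agilent design 074809 with probe positions on mouse build mm9, per the file headers, and shared a slide. Amplification from small and unequal pools can distort the ratio of abundant to rare transcripts, which 1 array per pool cannot show.

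The deposited scanner tables hold spot intensity on a linear scale, and per the file headers they were written by Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. The processed intensity was, per the file headers, background-subtracted and detrended within each array, with values at or below noise replaced by surrogates, and was not normalised between arrays. The tables also give each spot's p-value against its own background, computed by the scanner software per the file headers, and this p-value was not used here. The deposited series-wide table of intensity has 56605 probes and is also linear. Its sorted columns were the same within 0.0243%, so the authors' values are quantile normalised between the arrays, with a median of 57.95 in both columns. They followed the scanner values with r = 0.99997 on the log2 scale across probes on each array, and the differences between arrays with r = 0.997 across probes well above background on both, which leaves scale and direction known and shows no centring of genes.

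The log2 of the processed intensity was taken per spot, spots flagged as outliers were left out (88 on the wild-type and 84 on the knockout array), replicate spots of a probe were averaged, and each array's 75th percentile over probes was subtracted. That percentile corresponded to signals of 808 on the wild-type and 790 on the knockout array, and the median signal of probes was 57.6 and 58.3. Control spots were left out, and 56600 of 56605 probes were used. A gene's value was the mean over its probes that were well above background on both arrays, so a gene with dim and bright probes, as Mul1, is averaged over probes that can disagree. The lowest signal well above background was 12.9 on the wild-type array and 15.8 on the knockout array. Genes near that level have imprecise differences. Probes were named through a RefSeq gene table of assembly GRCm38.p6, which served for names only. By accession 32994 probes matched, by symbol 10224 and by synonym 520, and 12867 kept the name in the file, giving 37008 gene names.

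No test was possible with 1 array per genotype. Genes were counted by size, at least 2-fold apart. Each of 30 gene lists was described by its median difference and by the percentile of that median among the medians of 10000 random lists of equal size, drawn with replacement from 15511 protein-coding genes in 20 bins of mean signal. A list is called apart where the percentile is under 2.5 or over 97.5. The groups, the lists, the size rule, the rule for named genes and the alternatives were fixed before the data were examined. Named are Mul1, the 12 genes highest and the 12 lowest on the knockout array among genes brighter than the median, with an established symbol, no saturated spot and all probes on the same side, the 5 genes with the largest bound on each array alone, the extreme members of each list (up to 3 on each side), markers of other cell types at least 2-fold apart, and Gapdh, Actb, Gdf9 and Zp3. From the lists, the text gives a few of those members each, and the values of some members are not reported here. Genes of symbol families and of lists written later were chosen after values were seen and stand in the closing part.

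The scripts were first tested on simulated data, in which the knockout array was replaced by the wild-type values plus noise as wide as the central spread of the real differences at each signal level. Among 22894 genes run, of 50 genes per size given a difference of -2 or 2, 100% were called at least 2-fold apart. At differences of -1.5 and 1.5, 96% and 94% were called, and 1.94% of the 22694 unchanged genes were called as well. Of 200 simulated lists of 30 genes with no shift 7% lay outside the central 95% of random lists, and of 200 lists shifted by 0.3 all did.

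Alternatives were scaling on the median of detected probes, quantile normalisation, loess of the difference on signal (span 0.3), normexp background correction (offset 50), the authors' quantile normalised values, scaling on spike-in controls (7 probes), no filter or a stricter filter on dim probes (4 times each array's lowest signal well above background), the brightest probe per gene, no use of outlier flags, random lists unmatched on signal, list means, and another flag for signals above background. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.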

Results

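Gene expression was measured in unfertilised oocytes of C57BL/6 mice, from wild-type animals and from animals lacking Mul1, an E3 ubiquitin ligase of the mitochondrial outer membrane. Total RNA of 213 wild-type oocytes and of 123 knockout oocytes was amplified, labelled with Cy3 and hybridised to 1 single-colour Agilent mouse array per genotype, both on the same slide. The study's title concerns reactive oxygen species in Mul1-deficient oocytes and early embryo development, and the comparison of the arrays asks which transcripts differ between the genotypes. With 1 array per genotype the differences have no replicate check, no test across genes was made, and the number of arrays limits the precision of every value. Of 56600 gene probes, 37369 (66.0%) were well above background on the wild-type array and 36488 (64.5%) on the knockout array, with no saturated spot on either. For 296 probes printed at 10 spots each, the log2 difference between the arrays had a median SD between spots of 0.04 and a largest SD of 0.20, which describes spot noise only. All differences are given as knockout minus wild type on the log2 scale, after each array was set to its 75th percentile.

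Mul1 was lower on the knockout array at the probe for its RefSeq transcript NM_026689, which lies on chromosome 4 at 137995759 to 137995818 of mouse build mm9 and has the sequence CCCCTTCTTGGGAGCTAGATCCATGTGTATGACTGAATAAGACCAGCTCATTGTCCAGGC. Its signal was 3353 on the wild-type array and 1074 on the knockout array, a log2 difference of -1.61 or a 3.05-fold lower value, with signal errors given by the scanner software of 335.3 and 107.5. The knockout signal was still 67.9 times the lowest signal called well above background on that array. The other Mul1 probe, for the Ensembl transcript ENSMUST00000105815 at 137994263 to 137994322, read 19.3 and 23.1, a log2 difference of 0.29 at 1.5 and 1.46 times the lowest signal well above background. Averaged over both probes, Mul1 differed by -0.66. The labels do not state which part of Mul1 was deleted, so whether either probe lies inside it is unknown and the remaining knockout signal cannot be assigned to intact or truncated transcript.

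Most transcripts were alike on the arrays. Among 22894 genes well above background on both, the median difference was 0.03 and the values correlated across genes with r = 0.989, genes not being independent replicates. At least 2-fold differences were seen for 670 genes that were higher and 313 that were lower on the knockout array, 4.29% of those measured, with 1792 higher and 1188 lower at 1.5-fold and 76 and 23 at 4-fold. The split depended on the kind of transcript, with 489 higher and 123 lower among 15511 protein-coding genes and 130 higher and 171 lower among 5784 loci with no match in RefSeq. It also depended on signal, with 20 higher and 35 lower among the brightest 20% of genes and 263 higher and 78 lower among the dimmest 20%. Of 147 genes at least 2-fold apart that had several probes, 144 had all probes on the same side. Selection on the mean of the same probes favours such agreement, and a probe near 0 counts as agreeing. Gapdh differed by -0.05 to 0.12 over its 7 probes, and Actb by 0.00. The oocyte growth factor gene Gdf9 differed by -0.11, which became 0.04 when the arrays were scaled on spike-in controls, and the zona pellucida gene Zp3 by 0.41. With normexp background correction the counts were 212 higher and 116 lower, and scaling on the spike-in controls raised the median of all genes to 0.18, with 934 higher and 194 lower, or 82.8% against 68.2% of the genes apart being higher.

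**Figure D1:**
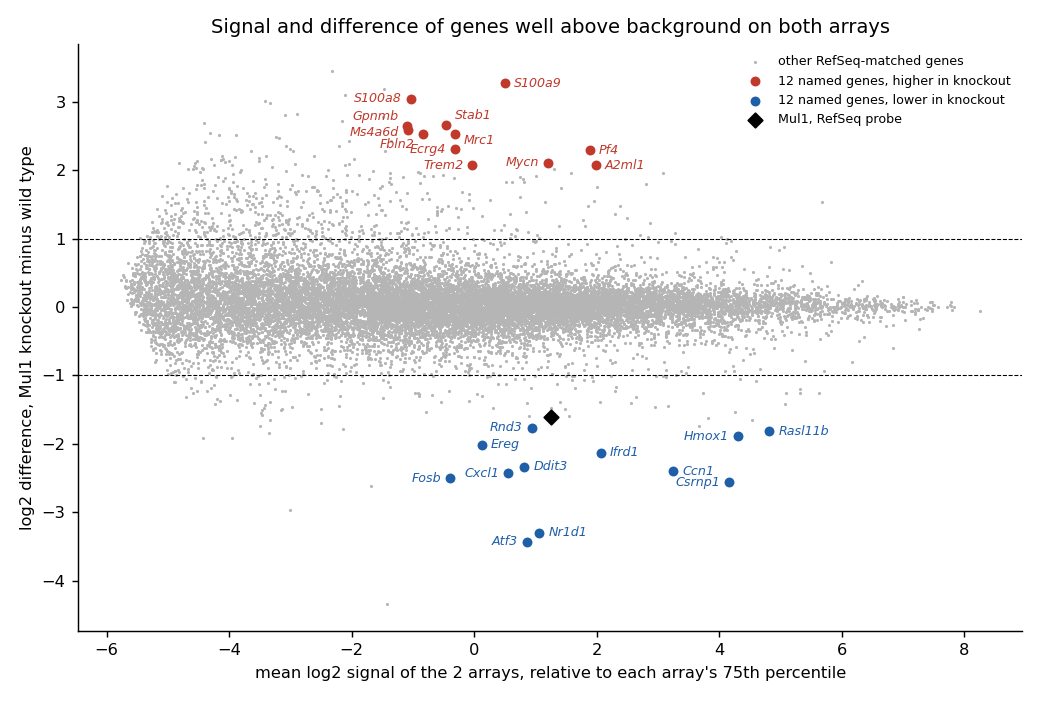
Log2 difference, knockout minus wild type, against the mean log2 signal of both arrays relative to each array's 75th percentile, for 17110 genes matched to RefSeq and well above background on both arrays (grey), with the 12 named genes highest (red) and the 12 lowest (blue) on the knockout array, the Mul1 RefSeq probe (black diamond) and dashed lines at 2-fold. S100a9 at 3.27 and Atf3 at -3.43 are the named genes farthest from 0, and the spread of the grey points is wider at low signal.

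Myeloid cell genes made up much of the group highest on the knockout array. S100a9 and S100a8, which encode the calprotectin subunits of neutrophils and monocytes, were 9.67-fold and 8.26-fold higher, with signals of 367 and 138 on the wild-type array and 3473 and 1111 on the knockout array. The S100a9 probe, for NM_001281852, lies on chromosome 3 at 90496573 to 90496632 of mm9 and the S100a8 probe, for NM_013650, at 90473778 to 90473837, and exon annotation of that build was not used here. The scavenger receptor gene Stab1 (6.34-fold), the macrophage glycoprotein gene Gpnmb (6.27-fold), Ms4a6d (6.00-fold), the mannose receptor gene Mrc1 (5.797-fold), the chemokine gene Pf4 (4.92-fold) and the microglial and macrophage receptor gene Trem2 (4.22-fold) were also higher. The remaining genes of this group were the extracellular matrix gene Fbln2 (5.804-fold), Ecrg4 (4.94-fold), the transcription factor gene Mycn (4.32-fold) and the protease inhibitor gene A2ml1 (4.22-fold). The fixed list of blood and immune cell markers had a median difference of 1.23, at percentile 100 of 10000 random lists matched on signal. Compared by means it lay 0.75 above such lists, again at percentile 100, and its members fell on both sides. Of 23 measured members 12 were at least 2-fold higher, and 5 at least 2-fold lower. Besides S100a9 and S100a8, the higher ones were the myeloid signalling adaptors Tyrobp at 2.02 and Fcer1g at 1.95, the complement genes C1qb, C1qa and C1qc at 1.82, 1.82 and 1.75, the antigen presentation genes Cd74 at 1.48 and H2-Aa at 1.29, and Cd68 at 1.45, Laptm5 at 1.42 and the lysozyme gene Lyz2 at 1.23. All 5 of the lower ones are red cell genes, with Hba-a2 at -1.66, Hba-a1 at -1.62, Hbb-bt at -1.39, Hbb-b1 at -1.23 and the haem synthesis gene Alas2 at -1.03.

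Interferon-response genes were higher together with these markers. The innate immune and interferon list had a median difference of 0.41 (percentile 100), with 28 of 32 measured members above 0 and 6 at least 2-fold higher, including the antiviral genes Oas2 at 1.91, Ifit1 at 1.39 and Oas1a at 1.36. The chemokine gene Cxcl10 was at least 2-fold lower at -1.46, and Ifi27 read -0.32 and Irf1 -0.28. The NF-kB list divided, with a median of -0.11 (percentile 0.530) that became 0.04 on the spike-in scale. Its adhesion and cytokine genes Vcam1 (2.35), Il1b (1.47) and Ccl2 (1.40) were at least 2-fold higher and Cxcl1 (-2.43) and the feedback regulators Tnfaip3 (-1.30) and Nfkbiz (-1.29) at least 2-fold lower.

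On the lower side, several of the named genes were immediate-early or stress-response genes, and others, such as Nr1d1, Rasl11b and Rnd3, were of neither kind. Atf3, a transcription factor gene of the stress response, was 10.8-fold lower at its probe for NM_007498, on chromosome 1 at 192994547 to 192994606 of mm9, with signals of 4799 on the wild-type array and 436 on the knockout array, and the clock repressor gene Nr1d1 was 9.82-fold lower, with signals of 5274 and 525. The immediate-early genes Csrnp1 (5.90-fold), Fosb (5.67-fold), Ccn1 (5.28-fold) and Ifrd1 (4.38-fold) were lower too, as were the chemokine gene Cxcl1 (5.39-fold), the pro-apoptotic stress gene Ddit3 (5.05-fold) and the EGF-like ligand gene Ereg (4.03-fold). Hmox1, the haem oxygenase induced by oxidative stress, was 3.69-fold lower, with signals of 30677 and 8121. The small GTPase genes Rasl11b (3.52-fold) and Rnd3 (3.39-fold) completed the named genes on this side. All 24 named genes were at least 2-fold apart in the same direction in all of their 240 values under other settings. They were selected for large differences and the settings reprocess the same 2 arrays, so this is no independent check.

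The integrated stress response and ER stress list had a median of -0.16 (percentile 0.0200), which was -0.01 on the spike-in scale, and 6 of its 29 measured members were at least 2-fold lower, including Atf3, Ddit3, the glutathione-degrading gene Chac1 at -1.47 and the ER chaperone gene Hspa5 at -1.26, while Gdf15 read 0.69 and Ddit4 0.59. With the brightest probe of each gene this list lay at percentile 18.3 and with a stricter filter on dim probes at 7.42, inside the central 95% of random lists. Heat shock proteins had a median of -0.12 (percentile 1.21), which became 0.04 on the spike-in scale, with none of 19 at least 1.5-fold apart, Bag3 at -0.42 and Cryab at 0.50. By the mean over the list (percentile 7.44) or without a filter on dim probes (2.86) heat shock proteins were not apart. The list of p53 targets and DNA damage genes was not apart from random lists at a median of -0.05 (percentile 4.30; 0.11 on the spike-in scale), although the growth arrest gene Gadd45g at -1.74 and the kinase gene Plk2 at -1.11 were at least 2-fold lower. By its mean (0.0200), with normexp or without a filter on dim probes (2.10 in both) that list was apart. Apoptosis regulators had a median of 0.16 (percentile 99.6; 84.2 by the mean), with Pmaip1 at 0.63, Casp2 at 0.56 and the survival gene Mcl1 at -0.63.

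The study's title names reactive oxygen species, and antioxidant enzymes were not apart from matched genes. Their median was 0.00 (percentile 30.8), and none of the 36 members was at least 1.5-fold apart, the extremes being the extracellular superoxide dismutase gene Sod3 at 0.54, Gpx6 at 0.38, Oxr1 at -0.35 and the cytosolic superoxide dismutase gene Sod1 at -0.34. The Sod1 value averages probes at -0.63 and -0.06, and Oxr1 probes ran from -0.54 to -0.06, so both sizes are uncertain. The median of the list was slightly below 0 after loess or normexp and 0.16 on the spike-in scale. The NRF2 and glutathione list was not apart either at -0.03 (percentile 9.09; 0.13 on the spike-in scale and above 0 with normexp), but Hmox1 at -1.88, the pathway's transcription factor gene Nfe2l2 at -1.46 and its partner Maff at -1.12 were at least 2-fold lower, and the list was apart by its mean (percentile 0.350) and without a filter on dim probes (2.43). The Nfe2l2 value averages 2 probes that disagreed, at -2.90 and -0.02, so its size is uncertain. ROS-producing oxidases had a median of 0.25 (percentile 98.4), with 2 of 17 at least 2-fold higher. Ncf1 read 1.15 and Cybb 0.92, both subunits of the phagocyte NADPH oxidase, while Maob read -0.41 and Nox4 -0.36. This list was apart in 7 of 12 alternative settings, and Ncf1 and Cybb were dim genes that differed in the same direction as the blood and immune cell markers.

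Mitochondrial transcripts differed by small amounts. All 11 measured mitochondrially encoded genes were below 0, with a median of -0.16 (percentile 0.16; -0.01 on the spike-in scale, where the members nearest to 0 lay above it), ND4L and ND1 lowest at -0.47 and COX2 nearest to 0 at -0.02. Nuclear-encoded subunits of oxidative phosphorylation lay on the other side, with a median of 0.07 (percentile 98.8), 52 of 76 above 0, none at least 1.5-fold apart, and extremes of 0.47 for Ndufa9 and -0.37 for Atp5g3. That list was not apart when random lists were unmatched on signal (percentile 79.9) or by its mean (95.3). Mitochondrial dynamics genes had a median of 0.06 (percentile 81.0), with Trak2 at 0.31, the fission gene Dnm1l at -0.15 and Yme1l1 at -0.22, and the mitophagy and autophagy list one of 0.04 (61.8), with Atg9a at 0.51 and Atg13 at -0.60. Genes of the outer membrane ubiquitin system had a median of -0.03 (percentile 10.8; 0.12 on the spike-in scale), with the deubiquitinase gene Usp15 lowest at -0.70 and Tomm6 at 0.24. Mitochondrial chaperones, proteases and biogenesis genes were at -0.05 (7.84; 0.10 on the spike-in scale), with Afg3l2 at -0.58 and Dnaja3 at 0.35. Mitochondrial ribosomal proteins were at 0.03 (66.0), with Mrps15 at 0.56 and Mrps31 at -0.48. The TCA cycle list was at 0.03 (61.8), with Pdha1 at 0.53 and Pdhb at -0.41, and the glycolysis list at 0.05 (73.4), where the regulator gene Pfkfb3 was at least 2-fold lower at -1.38 and the glucose transporter gene Slc2a3 read 0.9998, just under 2-fold higher. Several of these extreme members had probes that disagreed. Probes of Usp15 ran from -1.63 to 0.11, of Mrps31 from -1.02 to 0.05 and of Atp5g3 from -0.76 to 0.02. Those of Mrps15 ran from 0.10 to 1.02.

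**Figure D2:**
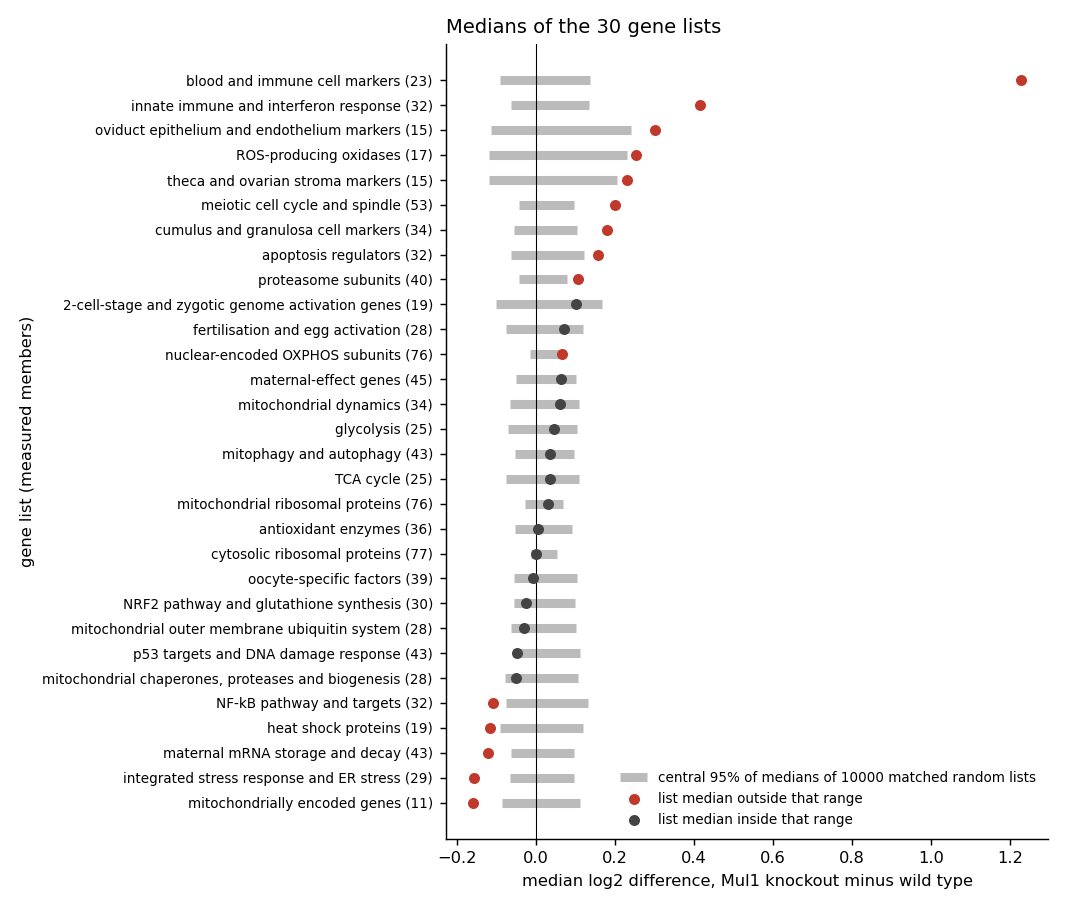
Median log2 difference, knockout minus wild type, of the measured members of each of the 30 gene lists (points) against the central 95% of the medians of 10000 random lists matched on size and mean signal (grey bars), with the number of measured members in brackets and no error between animals, as each genotype has 1 array. The medians of 15 lists lie outside the bars, with blood and immune cell markers farthest from 0 at 1.23 and antioxidant enzymes inside their bar at 0.00.

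Among the oocyte lists, meiotic genes and genes of maternal mRNA storage and decay were apart from matched genes, on opposite sides. Meiotic cell cycle and spindle genes had a median of 0.20 (percentile 100), with 42 of 53 above 0 and none at least 2-fold apart, Aurkb at 0.83, Cdc25b at 0.79, Anapc1 at -0.48 and Aurkc at -0.40. Genes of maternal mRNA storage and decay had a median of -0.12 (percentile 0.0800), which became 0.03 on the spike-in scale, with the m6A reader genes Ythdc1 at -0.90 and Ythdf2 at -0.43, Cpeb4 at -0.66 and Pabpn1l at 0.43. Oocyte-specific factors were not apart, with a median of -0.01 (percentile 17.9; 0.15 on the spike-in scale), a mean of 0.06, Nlrp14 at 0.55, Bmp15 at 0.53 and Oas1d at -0.23. Maternal-effect genes were not apart at 0.06 (84.8), with Ooep at 0.94, Nlrp5 at 0.77 and Rlim at -0.48, nor were fertilisation and egg activation genes at 0.07 (82.4), with the chloride channel gene Ano1 at 0.94 and the calcium release channel gene Itpr1 at -0.45. Itpr1 probes disagreed, from -1.17 to 0.10. Genes of the 2-cell stage and zygotic genome activation had a median of 0.10 (84.5) over 19 measured of 47, and the protease gene Ctsk, at 1.90, was the member at least 2-fold apart. Proteasome subunits had a median of 0.11 (99.8; 92.5 against unmatched lists and 97.3 by the mean), with Psmc4 at 0.42 and Psmc2 at -0.18, and cytosolic ribosomal proteins one of 0.00 (14.0), slightly below 0 in 3 of 6 other scalings, with Rpl12 at 0.17 and Rps27a at -0.31.

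Markers of the cells around the oocyte were present on both arrays. The cumulus and granulosa list had a median of 0.18 (percentile 99.99), with all 34 members well above background on both arrays, 23 above 0, the hyaluronan synthase gene Has2 at 1.16 and Ptx3 at 0.94 highest, and the EGF-like ligand genes Ereg at -2.01 and Areg at -1.02 and the steroidogenic gene Star at -0.96 lowest. By the mean over this list it was not apart (percentile 84.4). Theca and stroma markers had a median of 0.23 (98.5), with Tagln at 0.62, Pdgfra at 0.61 and Dcn at -0.94, and were apart in 9 of 12 alternatives. Oviduct epithelium and endothelium markers had a median of 0.30 (99.2) and were apart in 10 of 12, with the oviductal glycoprotein gene Ovgp1 at 1.54 and signals of 24266 and 69104, the endothelial receptor gene Kdr at 1.13, Epcam at 1.09 and Upk1b at -0.28. The distance of this list from random lists ran from 0.12 to 0.33 over those alternatives. In total 15 of the 30 lists lay outside the central 95% of random lists, where 1.5 would do so if genes were independent. Genes of a list are not independent, so these percentiles describe this pair of arrays and do not test the genotype.

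**Figure D3:**
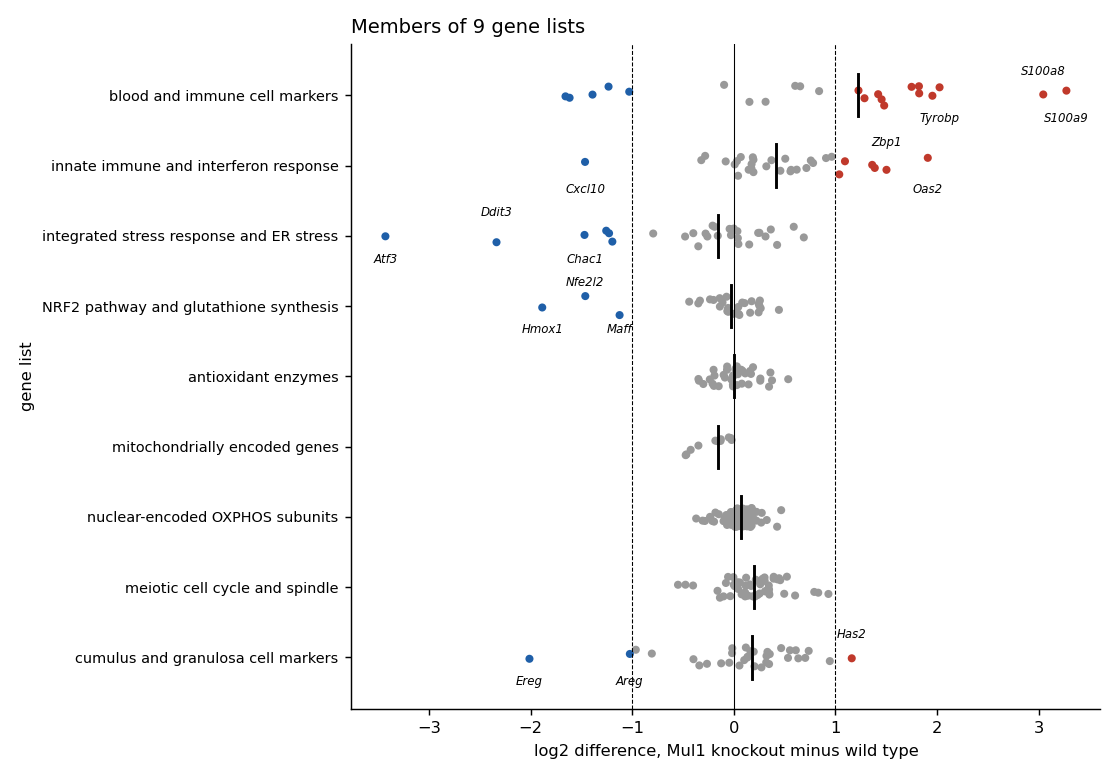
Log2 difference, knockout minus wild type, of each measured member of 9 gene lists (points), at least 2-fold higher in red, at least 2-fold lower in blue and others in grey, with black bars at the list medians and dashed lines at 2-fold. In the blood and immune cell list 12 members are red and the 5 blue ones are the haemoglobin genes and Alas2, while all 36 antioxidant enzymes are grey.

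Transcripts well above background on a single array numbered 820 for the knockout and 1267 for the wild type, and 12011 gene names were on neither. Folds for these are lower bounds, the bright signal against the higher of the dim array's lowest signal well above background and the dim probe's own. The bound reached 2-fold for 250 of the knockout genes and 70 of the wild-type genes. That lowest signal was 12.9 on the wild-type array and 15.8 on the knockout array. The higher level on the knockout array favours more genes on the wild-type array alone, with smaller bounds. Neither pair of counts therefore compares the genotypes on an equal footing. On the knockout array alone, the retinoic acid hydroxylase gene Cyp26a1 was at least 11.8-fold higher, the leukocyte gene Ms4a6b 10.04-fold, the monocyte chemoattractant gene Ccl12 8.89-fold, the citrate transporter gene Slc13a5 7.86-fold and the interferon-induced gene Ifit3 7.45-fold. On the wild-type array alone, Apol8 was at least 18.8-fold higher, the adrenaline synthesis gene Pnmt 6.45-fold, Reg1 3.58-fold, Tex45 3.03-fold and the transcription factor gene Tbr1 2.73-fold. These signals were dim, from 93.6 to 148 for the 5 knockout genes and from 44.4 to 304 for the 5 wild-type genes, and with normexp 8 knockout and 2 wild-type genes had a bound of 2-fold. With another flag for signals above background 1632 genes were on the knockout array alone, and 1025 knockout and 527 wild-type genes had a bound of 2-fold.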

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

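The comparison of control probes was chosen after the main results were seen. Control probes were left out of the comparisons in the main setting, and spike-in control probes served for an alternative scaling. The rule looked only for control probes well above background on the knockout array and at least 2-fold higher there. Of 139 control probe names 1, ETG10_13482, which was not used for that scaling, met it, with a log2 difference of 1.77. ERCC-00096_179 read 1.14 but was mostly not well above background, and the lowest difference was -0.58, for DCP_22_7. The 12 spots of ETG10_13482 had a mean signal of 24.8 (SD 8.09 between spots) on the wild-type array and 77.6 (SD 14.7) on the knockout array, and the SD of the log2 difference between spots was 0.72. Spots on an array are not replicates of a genotype, and the target of this probe is not given in the sources used here. No technical or biological explanation was tested for it.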

How the results depend on the processing

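No alternative was chosen after the data were seen. No paired analysis was possible because each genotype has 1 array and the replicate numbers were given in accession order. All 24 named genes were at least 2-fold apart in the same direction in 240 of 240 alternative values, the smallest size being 1.61 on the log2 scale. Their selection for large differences on the same arrays made that outcome likely. Across list shifts (each list's median minus that of its matched random lists) 329 alternative values moved by less than the SD of random lists, and 31 moved by more. Scaling on the median of detected probes or on spike-in controls adds a constant to every gene, which cannot move a shift, so those values were fixed in advance. None of the 15 lists called apart changed the sign of its shift, whereas the shifts of antioxidant enzymes, mitophagy and autophagy, the TCA cycle, glycolysis, oocyte-specific factors, the 2-cell stage and both ribosomal lists, none of them apart, changed sign under at least 1 alternative. The medians themselves of the heat shock, maternal mRNA and NF-kB lists, all called apart, went from below to above 0 on the spike-in scale. The mean difference of the Mul1 probes was -0.71 after quantile normalisation and with the authors' values, -0.74 after loess, -0.72 with normexp and -0.51 on the spike-in scale, where its RefSeq probe differed by -1.46. With the stricter filter or the brightest probe Mul1 differed by -1.61, since its dim probe then drops out. The counts at 2-fold were 212 higher and 116 lower with normexp, whose offset shrinks the differences of dim genes by construction. They were 2764 and 1327 without a filter on dim probes and 338 and 195 with the stricter one, as more or fewer dim genes enter. Scaling on the spike-in controls gave 934 higher and 194 lower and moved the median of all genes from 0.03 to 0.18. Shifts of the main lists that moved were those of cumulus and granulosa markers, to 0.0634 by list means and 0.1106 with normexp, of antioxidant enzymes, to 0.0232 without a filter, and of nuclear-encoded oxidative phosphorylation subunits, to 0.0709 with the brightest probe; the cause was not tested. Of genes on a single array, 2 wild-type and 8 knockout genes had a bound of 2-fold with normexp. With the other flag for signals above background 1632 genes were on the knockout array alone, and 1025 knockout and 527 wild-type genes had such a bound, and the cause was not tested. The counts by flag do not depend on normexp or on the authors' values, so none was computed there. Signal over background limits the dim genes, since 6.67% of genes dimmer than the median and 1.91% of brighter ones were at least 2-fold apart.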

Other observations

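The grouping of genes by symbol family and the tests on red cell genes, on the share of oocyte RNA, on cumulus cells and on signal dependence were chosen after the results were seen, and all genes named here outside the fixed rule were chosen after their values were seen. Among 189 families of protein-coding genes that share the letters of their symbol, 34 had medians outside the central 95% of matched random lists. Some would lie outside by the rule alone, as 7% of simulated lists with no shift did. Genes of a family are not independent, so this number does not test the genotype. Glandular kallikreins had the highest median, 1.13 over 13 measured genes, and 8 were at least 2-fold higher on the knockout array, with Klk1b4 at 2.15 and Klk1b24 at 1.70. Their signals were dim, 21.8 and 28.7 on the wild-type array for these, the median was 0.43 at the lowest of the other scalings, and these close paralogs can share probes, so their values are not independent. Chemokines of the Ccl family had a median of 0.64 with 6 of 14 at least 2-fold higher, Ccl8 at 3.46 and the bright Ccl6 at 1.80. C-type lectins had a median of 0.67 with 7 of 20, Clec4a3 at 2.72 highest and a median of 0.27 at the lowest of the other scalings, and Toll-like receptors one of 0.68 with 3 of 10, Tlr1 at 2.29 highest and a median of 0.40 at the lowest. All 4 of these medians were above 0 under each scaling.

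The Rbm, Srsf and Klf families lay on the lower side by smaller amounts. The RNA-binding Rbm family had a median of -0.16 (percentile 0.0100; -0.01 on the spike-in scale), with 10 of 34 above 0, Rbm25 at -0.87 and Rbm39 at -0.83. Splicing factors of the Srsf family had a median of -0.16 (percentile 0.99; -0.01 on the spike-in scale), with Srsf5 at -0.55 and Srsf11 at -0.43. The Klf family of transcription factors had a median of -0.21 (percentile 0.05; -0.05 on the spike-in scale), with 4 of 16 above 0 and Klf6 at -1.26.

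Macrophage genes and some other leukocyte genes were higher on the knockout array, and RNA of macrophages or monocytes in that pool is a candidate explanation, stated as a hypothesis. In a list of further macrophage genes written before their values were looked at, the median of 51 measured genes was 1.11 (bootstrap 95% interval over genes 0.78 to 1.63), 45 were above 0 and 29 at least 2-fold higher, among the abundant ones Ctss (signals of 3465 on the wild-type and 13171 on the knockout array) and Ccl6 (3014 and 10285), although the bright Lgmn (-0.12) and Cd52 (-0.09) were not higher. Carried-over whole blood in the knockout pool would raise red cell genes, and haemoglobin genes and Alas2 had a median of -1.39. That prediction was written after these values were seen, so it is no independent test. Further erythroid genes did not repeat the fall, with 5 of 7 above 0, but at 0.13 lay well under the macrophage genes. A lower share of oocyte RNA would raise other cell types alike. The cumulus and granulosa list, at 0.18 (0.06 to 0.33), lay well under the macrophage genes, which argues against it as the only source. A contribution stays open, since the medians of theca and stroma and of oviduct and endothelium markers were above 0 as well. Further lists had medians of 0.34 for neutrophil genes (17 measured, -0.15 to 0.85, percentile 99.7), 0.29 for T, B and NK cell genes (16, 0.16 to 0.94, percentile 95.1, not apart) and 0.13 for erythroid genes (7, -0.18 to 0.27, percentile 75.2, not apart), and the labels name no sort or gate. Whether such cells came with the knockout pool by collection or by genotype was not tested.

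Immediate-early genes and some stress-response genes, 6 of 29 in the integrated stress response list at 2-fold, were lower on the knockout array. In a list of further immediate-early genes written before their values were looked at, 37 of 42 were below 0, with a median of -0.52 (-0.73 to -0.38), 11 were at least 2-fold lower, led by Sik1 at -1.59 and Socs3 at -1.53, and 2 at least 2-fold higher, Id1 at 1.36 and Dusp2 at 1.19. Fewer cumulus cells in the knockout pool would lower the cumulus and granulosa list, whose median was 0.18, although by its mean that list was not apart (percentile 84.4). That prediction was written after the median was seen, and members of the list went both ways. The list therefore shows no general fall but cannot decide on the number of cumulus cells. A different time of day may contribute, since clock genes in phase with Nr1d1 had a median of -0.41 (-0.93 to -0.08, 8 measured), but those of opposite phase read -0.14 (5 measured) where that explanation predicts higher values, and these lists are too small to decide. Handling or collection that sets off immediate-early genes and an effect of the genotype cannot be told apart, because each genotype has 1 pool and both would give the value of -0.52.

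The number of genes at least 2-fold apart could also come from technical sources. Around the targeted locus, 4.93% of 406 genes within 10 Mb of Mul1 were at least 2-fold apart (exact 95% binomial interval 3.04 to 7.51) against 4.28% of the other placed genes. The 20 near Mul1 included the leukocyte genes C1qa and Laptm5. No excess that DNA of another strain would give was seen in that window. The window holds few of the placed genes, so this cannot speak to the total number or to such DNA elsewhere. A signal-dependent offset between the arrays was seen, with a median difference of 0.11 in the dimmest 20% of genes and 0.02 in the brightest 20%. The DarkCorner control spots, too dim to be well above background, read 0.34. Loess removes the mean trend, and afterwards dim protein-coding genes still had a ratio of 5.35 higher to 1 lower. Unmatched loci of the same part had a ratio of 0.639. These ratios argue against the offset as the only source of that excess, but it may contribute to the counts. A background of C57BL/6J against C57BL/6N cannot be told apart from a common one here. Nnt, which differs between these substrains, read -0.17 at its brightest probe and 0.15 and 0.31 at its dimmer ones. The place of these probes relative to the missing exons is unknown. With 1 pool per genotype, variation between pools and the effect of the genotype stay open for all of these genes.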
